A study of Drosophila melanogaster with 2 samples.

How the data were processed

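Binding of Ets98B-eGFP was measured by ChIP-seq in 2 biological replicates of whole pupae, with an antibody against GFP and chromatin sheared by sonication to fragments of 200 to 800 bp, per the labels. The labels place both samples in 1 group and number the replicates. The group held no sample of another condition, and no control was analysed here. All comparisons were therefore made within the peaks of the tagged factor, against random placements, flanking sequence or other genes.

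The authors deposited peak lists on the dm6 build, per the labels. Aligner, peak caller and their versions are not given in the sources used here. Per the authors' file lists, each replicate has a ranked and a thresholded list made from its own alignment and a further file, and series-level lists were made from both alignments and that file. The same file is a parent of the tracks of fold change over control, so it was taken to be the control. Thresholded lists have 1 more parent file, whose role is not given in the sources used here. Signal tracks were not used here. The deposited signal column holds the caller's signal value for each peak, whose scale is not given in the sources used here. The deposited score column holds a scaled irreproducible discovery rate (IDR) score of at most 1000. The deposited −log10 columns hold the q-value of each peak and, in ranked lists, the global IDR. The IDR compares the ranks of peaks between replicates or partial data sets.

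Before use, the lists were compared. All 7157 conservative peaks are in a ranked list of 38614 peaks, and their lowest score of 830 corresponds to an IDR of at most 0.0100. In that ranked list 7335 peaks reach this score, so that the authors removed 178 others by a step the sources used here do not describe. The other series-level list held 8788 peaks, and 222 others that reached the same score were absent from it. For the thresholded lists of replicates 1 and 2 the numbers removed were 125 and 236. Most peaks have a fixed width (380 bp in 4221 of the conservative peaks), with the summit given by the authors, and 16 conservative peaks repeat an interval with another summit. Each was kept. In the 2 ranked series-level lists, 16 columns that hold values of the compared lists were not used, because no label assigns them to a replicate. No total of reads is given, so depth per sample was unknown and no interval for it could be made. Wilson intervals for shares of peaks and genes cover counting error only.

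Peaks on the 7 main arms (2L, 2R, 3L, 3R, 4, X, Y) were used, and every peak and gene lay within the arm lengths of the reference FASTA. Genes came from Ensembl release 115 (BDGP 6.54), which has dm6 coordinates, and sequence from the Release 6 reference assembly. A peak was counted at a TSS if its summit lay within 500 bp of the TSS of any transcript of a protein-coding gene. Summits were classed in the order TSS window, 5′ UTR, coding exon, 3′ UTR, intron, exon of another gene type, and intergenic, with non-coding exon sequence of protein-coding genes that is not 5′ UTR counted as 3′ UTR. TSS and class shares were set against 1000 random placements of the summits on the same chromosome, outside runs of N, with a two-sided permutation p. Overlap of replicates needed at least 1 bp, was set against 1000 random placements in the same way, and gave the same numbers in bedtools 2.31.1 (4563 and 4762 peaks).

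Each of 23 sequence words, 6 of them ETS words, was searched on either strand in windows of 101 bp at the summit and centred 500 bp to each side. Summit and flank were compared within peaks by an exact McNemar test against each side, and the larger p was kept, or 1 where the sides differed in direction. For 25 gene lists with 877 genes in all, the share of genes with a summit at a TSS was compared with all other protein-coding genes by Fisher's exact test, and by a Cochran-Mantel-Haenszel test in 4 strata of the number of TSSs. Of the 370 list entries, 4 were matched by an older symbol and 4 were not matched. The lists covered the ETS family, ecdysone response, EGFR and related receptor signalling, Notch, Wnt, Hippo, JNK and AP-1, apoptosis, Hox, segmentation factors, ribosomal proteins, proteasome, nuclear oxidative phosphorylation genes, muscle, neuron, glia, hemocyte, Toll and Imd immunity, cuticle proteins, chemoreceptors, cell cycle, germline, circadian, trachea, and eye and imaginal discs. Some genes belong to more than 1 list.

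Median signal values were compared by a two-sided permutation test with 100000 resamples, and peaks per arm by exact binomial tests against the share of sequence. p-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Correlations of signal across overlapping peaks were Spearman's rho and Pearson's r on log values. Replicate signal values given for a named gene are those of the peak in that replicate's ranked list with a summit within 100 bp.

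The tests, gene lists, words, most alternative settings and the rule for named genes were chosen before the data were examined. The rule took the genes with a TSS at the 15 strongest peaks (or the nearest gene), each ETS-domain gene, up to 4 members with the highest signal of each list that differed from other genes and up to 2 of each other list. Genes named on chromosome 4 were chosen after their values were seen. Alternative settings were the other series-level set, the peaks of each replicate alone, the stronger peaks, other TSS windows, whole intervals, other overlap rules, other word windows and flanks, gene bodies another gene background and expectation per arm by TSSs. The 500 strongest peaks, flanks matched on GC and repeated intervals counted once were added after the data had been seen. Matched flanks were drawn at random, without repeats, from windows 300 to 1000 bp from the summits of all peaks. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

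The tests of TSS share, words, gene lists, overlap of replicates and signal were tried on simulated data; the tests of arms, of single annotation classes and of the closing section were not. With random peaks, the TSS test gave p = 0.989 (permutation) and 0 of 23 words were called. Summits placed at random do not differ from their flanks in GC or coding share on average. How such differences affect the word test was therefore not tried. With 20% of 7157 random peaks moved onto TSSs, a share of 29.0% was found where 29.2% was set. A word planted in 200 windows was found in 201.5 windows above the flanks. A list raised to a share of 60% among 13968 genes was found at 60.4% and was the 1 list called.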

Results

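Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster pupae aged 2 days that carried Ets98B fused to the green fluorescent protein eGFP. Ets98B is a transcription factor with an ETS DNA-binding domain, and chromatin bound by the fusion protein was recovered with an antibody against GFP. The samples were 2 biological replicates of 1 group, so the data address where peaks lay in the genome and how well the replicates agreed. The conservative peak set made by the authors from both replicates held 7157 peaks. Replicate 1 had 5851 peaks of its own, 5850 of them on the main chromosome arms, and replicate 2 had 7963. The read depth of the samples was unknown, because the peak lists hold no read counts. Wilson intervals cover the counting of peaks or genes only.

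Most peaks lay at transcription start sites (TSSs) and in introns, and few lay in protein-coding sequence. The summits of 2839 of the 7157 peaks (39.7%, 95% Wilson interval 38.5 to 40.8%) were within 500 bp of the TSS of a protein-coding gene, against 11.5% for random placements on the same chromosomes, a ratio of 3.46. The share was 36.9% in replicate 1 and 42.7% in replicate 2 (39.8% ± 4.10, SD, n = 2), and random placements gave 11.5% for each. Beyond the TSS windows, introns held 3075 summits (43.0%, expected 40.3%) and intergenic sequence held 1001 (14.0%, expected 27.8%). Coding exons held 28 summits (0.391%, expected 13.9%), and 3′ UTRs held 58 (0.810%, expected 4.55%). With TSS windows included, 79 summits (1.10%) fell in coding sequence, which makes up 16.7% of the sequence of the main arms.

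The TSS share differed from that of the 1000 random placements (two-sided permutation p = 0.001, the smallest they can give). The shares of coding exons, 3′ UTRs, introns and intergenic sequence also differed (permutation tests, adjusted p = 0.0014 for each, Benjamini-Hochberg over 7 classes). The 5′ UTR share of 0.838% (expected 0.799%) and the share in exons of other gene types of 1.34% (expected 1.16%) did not differ, with adjusted p of 0.742 and 0.206. The excess in introns was small and did not pass in the peaks of replicate 2 alone (41.2%, permutation test, adjusted p = 0.0874). The 5′ UTR share passed in replicate 2 alone (1.09%, adjusted p = 0.0084) and the share in exons of other gene types in replicate 1 alone (88 peaks, adjusted p = 0.0245) and in the other series-level set (125 peaks, adjusted p = 0.0257), all by permutation tests. In coding exons, both replicates were far below the random share, at 0.222% and 0.527% (0.375% ± 0.216, SD, n = 2).

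**Figure D1:**
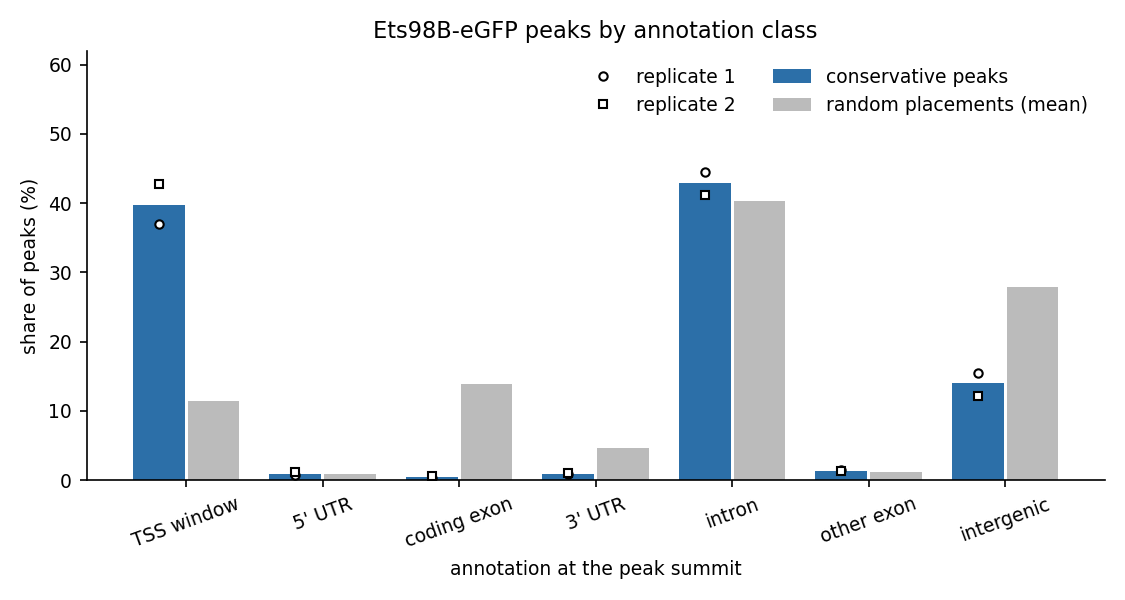
Share of peaks (%) by annotation class at the summit. Blue bars are the 7157 conservative peaks, grey bars the mean of 1000 random placements, and circles and squares the peaks of replicates 1 and 2; the TSS window held 39.7% of peaks against 11.5% at random, and coding exons 0.391% against 13.9%.

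Most of the 15 peaks with the highest signal values lay at TSSs. The strongest peak lay in an intron of CG11050 (2L, 6612330 to 6613033, dm6), 1023 bp from the nearest TSS, with a signal value of 3728 in the conservative set, 1539 in replicate 1 and 2136 in replicate 2. The next was at the promoter of Ugalt, which encodes a UDP-galactose transporter (X, 2703694 to 2704071), with 3211 in the conservative set, 1589 in replicate 1 and 1646 in replicate 2. The peak ranked 4 was at the TSS of PNPase, the gene of polynucleotide phosphorylase (3R, 31404489 to 31404826; signal 2239). Others of the 15 strongest were at the TSSs of CG14100 (signal 2456), of CenG1A and the mitochondrial ribosomal protein gene mRpS23, which shared a peak (2171), of CG18549 (2155), of Tcs5 and the ESCRT-III gene CHMP2B (1972), and of CG7601 and the complex I assembly factor gene CIA30 (1940).

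The small heat shock protein gene Hsp27 (3L, 9383730 to 9384109; signal 1771) and the Polycomb group gene ph-p (X, 2136965 to 2137541; signal 1716) also had a TSS peak among the 15. The remaining strong peaks were farther from TSSs. Intergenic summits lay 11920 bp from CG13323 (signal 1925), 5733 bp from eEF1gamma, a translation elongation factor gene (1849), and 3761 bp from CG31668 (1809). Intronic summits lay in CG32486, 5720 bp from the nearest TSS, that of CG16753 (1880), and in CG32772 (1874). Each of the 15 peaks had a summit within 100 bp in the ranked list of each replicate, so that none rested on 1 replicate.

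Peaks at TSSs were not distinguishable in strength from the others. The median signal value was 133 for the 2839 peaks at a TSS and 129 for the 4318 other (distal) peaks, a difference of 3.87 (two-sided permutation test, 100000 resamples, p = 0.144). Within replicate 1 the medians were 71.7 and 71.0 (p = 0.588), and within replicate 2 they were 69.9 and 69.4 (p = 0.624), by the same permutation test. The signal value is the authors' value for each peak and its scale is not given in the sources used here. With the other series-level peak set, the difference was 5.03 and passed the threshold (permutation p = 0.0100).

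The tagged gene itself held peaks. Ets98B (FBgn0005659; 3R, 27736538 to 27748366, plus strand) carried 3 peaks. The strongest was in an intron (27738368 to 27738574), 1952 bp from the nearest TSS, with a signal value of 288 in the conservative set, 136 in replicate 1 and 159 in replicate 2. The others were in the windows of its 2 annotated TSSs, at 27736403 to 27736782 (signal 119 in the set, 40.1 in replicate 1 and 82.1 in replicate 2) and at 27742699 to 27743078 (99.9 in the set, 46.0 and 70.1 in the replicates). Reads from the transgene and from the native gene were not told apart here.

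**Figure D2:**
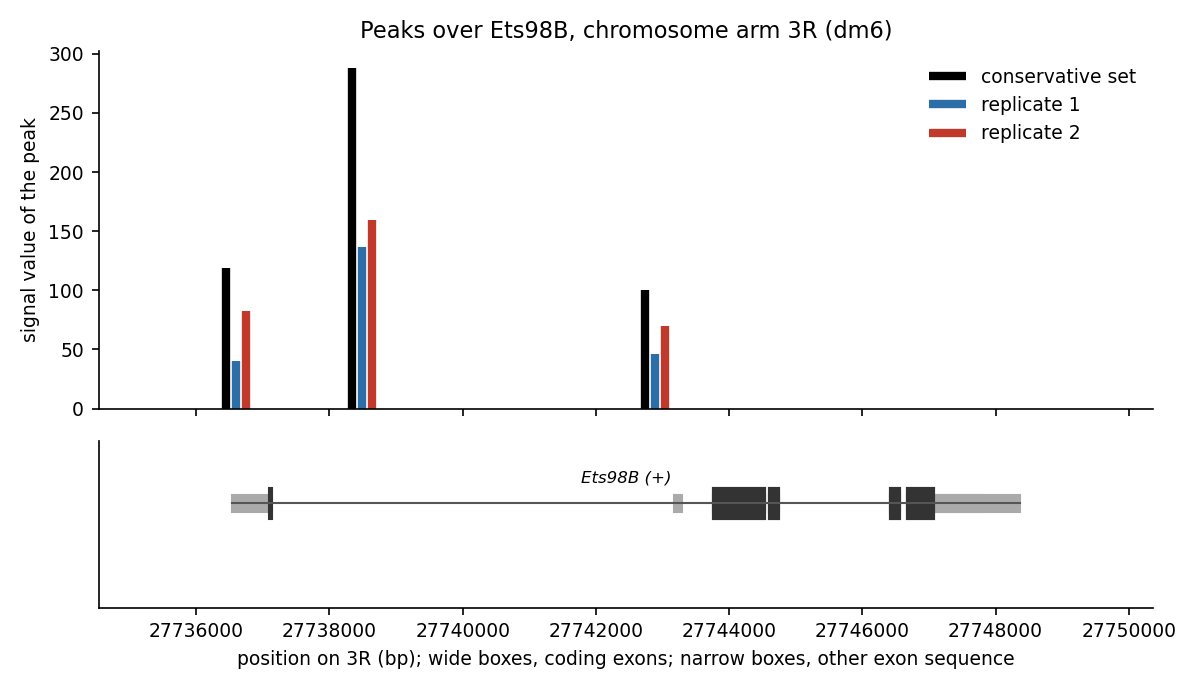
Peaks over Ets98B on 3R (dm6). The vertical axis is the signal value of each peak in the conservative set (black), replicate 1 (blue) and replicate 2 (red), with bars set side by side around each summit; below, wide boxes are coding exons and narrow boxes other exon sequence, and the strongest of the 3 peaks, at 288, lies in an intron.

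Of the 8 ETS-domain genes of the fly list, 5 had a peak at a TSS (62.5%, 95% Wilson interval 30.6 to 86.3%), against 21.4% of other genes. They were Eip74EF (signal 260.5 at 3L, 17619398 to 17619658), pnt (216 at 3R, 23295441 to 23295538), Ets21C (209 at 2L, 552575 to 552669), Ets98B and aop (77.8 at 2L, 2161393 to 2161772). The genes pnt and aop encode the activating and repressing ETS effectors of receptor tyrosine kinase signalling. Ets65A, Ets96B and Ets97D had no peak within the gene or 1000 bp of it. This share missed the threshold after adjustment (Fisher's exact test, adjusted p = 0.0587), and the TSS peak of aop with the highest signal had no matching summit in the ranked list of replicate 1.

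Genes with a peak at a TSS, called bound here, were more frequent among ribosomal protein genes than among other genes under all settings tried. Receptor tyrosine kinase signalling genes and ecdysone response genes were bound more often in the conservative set. With the peaks of replicate 1 alone their shares were also higher, but neither passed the threshold. The ecdysone excess in the conservative set did not pass once the number of TSSs per gene was taken into account. In all, 2995 of 13968 protein-coding genes were bound (21.4%, 95% Wilson interval 20.8 to 22.1%, and 20.8% ± 4.24, SD, n = 2, in the replicates). Of 22 genes of the response to ecdysone, the steroid that drives metamorphosis, 14 were bound (63.6%). They included Eip93F (signal 432 at 3R, 21972162 to 21972452), tai, a coactivator of the ecdysone receptor (313), Eip75B (278) and Eip74EF. Of 31 genes of EGFR and related receptor signalling, 17 were bound (54.8%), among them csw, which encodes a tyrosine phosphatase (362 at X, 2107848 to 2108091), the EGFR ligand gene spi (284), pnt and the FGF gene bnl (182). Of 92 ribosomal protein genes, 50 were bound (54.3%), with RpL34b (396), RpL32 (359), RpL7 (340.2) and RpL41 (295) the strongest.

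These 3 shares were above that of other genes, with odds ratios of 6.44, 4.47 and 4.42 (Benjamini-Hochberg over 25 lists). Adjusted p was 1.44e-04, 2.39e-04 and 5.59e-11 by Fisher's exact tests, and 0.119, 0.00461 and 8.30e-09 by asymptotic Cochran-Mantel-Haenszel tests stratified by the number of TSSs per gene, which the ecdysone list did not pass. The stratified odds ratios were 2.71, 3.46 and 3.65. With the peaks of replicate 1 alone, 7 ecdysone genes and 11 receptor signalling genes were bound, and neither list passed (Fisher's exact tests, adjusted p = 0.237 and 0.0840). The odds ratios there were 2.15 and 2.54, and 0.930 and 1.92 with stratification. Neither passed when the background was genes with a TSS peak in the ranked list (adjusted p = 0.116 and 0.235), and receptor signalling did not with the stronger conservative peaks (adjusted p = 0.291, Fisher's exact tests).

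Cuticle protein and chemoreceptor genes were nearly free of TSS peaks. Of 121 cuticle protein genes 3 were bound (2.48%), namely Cpr73D (signal 129), Cpr51A (108) and Cpr97Eb (81.3). Of 179 odorant, gustatory and ionotropic receptor genes 1 was bound (0.559%), Ir60e (96.3). Both shares were below that of other genes (Fisher's exact tests, adjusted p = 1.75e-08 and 2.30e-16), also in the asymptotic test stratified by number of TSSs (2.34e-04 and 3.80e-08). Both were low in each replicate, with 1 cuticle gene in replicate 1 and 3 in replicate 2, and 1 chemoreceptor gene in each.

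The other 19 lists did not pass. Hippo pathway genes were bound in 7 of 14 cases (Fisher's exact test, adjusted p = 0.0606), with app (signal 449) and Mer (289) the strongest, and Wnt pathway genes in 9 of 22 (40.9%, adjusted p = 0.112, same exact test), with sgg, which encodes the GSK3 kinase (679), and nkd (343). The Hippo list passed in the peaks of replicate 1 alone (adjusted p = 0.0377) and of replicate 2 alone (9 genes, adjusted p = 0.00619, exact tests), and in the other series-level set (adjusted p = 0.0348, exact test). It also passed with the 3578 strongest peaks and with a TSS window of 1000 bp (exact tests, adjusted p = 0.0205 and 0.0453). The Wnt (12 genes), Notch (11) and Toll and Imd (10) lists passed with the peaks of replicate 2 (exact tests, adjusted p = 0.00655, 0.0379 and 0.0499), but Toll and Imd did not in the stratified asymptotic test (adjusted p = 0.198). The Wnt and the Toll and Imd lists also passed with the other series-level set (exact tests, adjusted p = 6.85e-04 and 0.0330), and Wnt and Hippo with summits anywhere in the gene or within 1000 bp (exact tests, adjusted p = 4.60e-04 and 0.00171). None of the 8 Hox genes was bound (95% Wilson upper bound 32.4%, exact test, adjusted p = 0.402). For the Notch pathway the count was 7 of 23 (numb 357, mam 179.6), for Toll and Imd immunity 8 of 21 (cact 361, pll 294), for JNK and AP-1 4 of 12 (kay 163, egr 154), for apoptosis 3 of 12 (hid 303, Diap1 128), for the cell cycle 10 of 30 (Dp 615, Mcm2 170) and for segmentation factors 5 of 21 (hb 543, btd 131). All of these comparisons were Fisher's exact tests, and the lists of this group named so far had adjusted p between 0.0606 and 0.824.

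Lists for tissues, cell types and cellular machinery did not pass either in the conservative set. The counts were 7 of 23 for eye and imaginal disc genes (Dll 1300, sd 244), 5 of 14 for glia (moody 1135, loco 409.6), 3 of 22 for neurons (elav 724, Sh 271), 4 of 25 for muscle (sls 503, Zasp52 240.5), 4 of 11 for trachea (dnr1 191, bnl), 2 of 15 for hemocytes (ush 239, crq 136) and 3 of 17 for the germline (bgcn 165, wun2 100.4). For circadian genes the count was 4 of 10 (cry 188, dco 182), for nuclear genes of oxidative phosphorylation 14 of 87 (ND-ASHI 742, ND-MWFE 279) and for proteasome subunits 6 of 48 (Rpn3 202, Prosalpha3 156). Their adjusted p by Fisher's exact test lay between 0.361 and 1. With the peaks of replicate 2, the neuron and muscle lists did not pass by Fisher's exact tests (adjusted p = 0.238 and 0.575), but were lower than other genes by the asymptotic tests stratified by number of TSSs (odds ratios 0.105 and 0.239, adjusted p = 0.00482 and 0.0136). The stratified tests, which unlike Fisher's are not exact, gave an adjusted p of 0.0633 for each in the conservative set and of 0.138 and 0.143 in replicate 1.

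**Figure D3:**
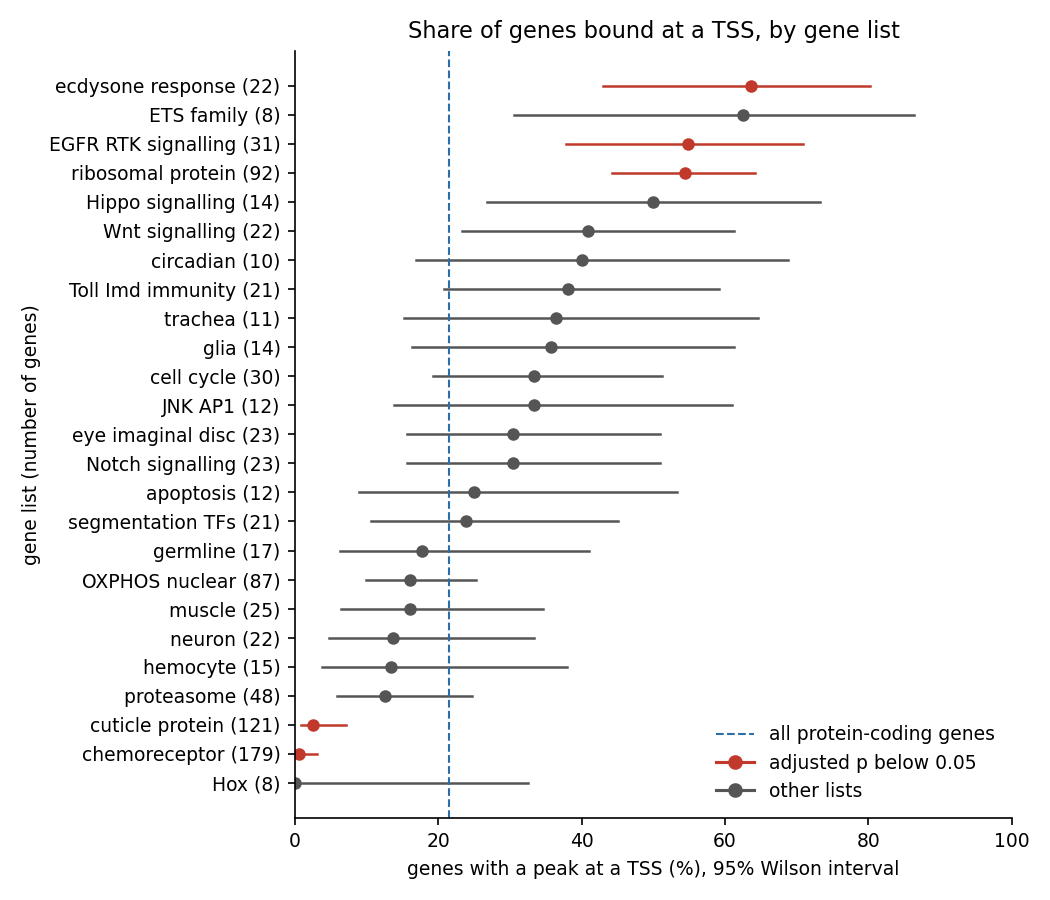
Share of genes (%) with a peak at a TSS in each of 25 gene lists, with 95% Wilson intervals and the number of genes in brackets. Red marks lists that differed from other genes after adjustment, grey marks the others and the dashed line is the 21.4% of all protein-coding genes; ecdysone response, receptor signalling and ribosomal protein genes lie above the line and cuticle protein and chemoreceptor genes below it.

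ETS binding words were not enriched at peak summits. The core GGAA occurred within 50 bp of 49.1% of summits and in 55.1% of flanking windows centred 500 bp away, a ratio of 0.891. GGAT, which the vertebrate relative SPDEF also binds, occurred at 30.9% of summits and in 39.3% of flanks (ratio 0.788). The longer forms MGGAAR (15.9% against 18.7%), MGGATR (7.08% against 10.5%) and CCGGATG (0.168% against 0.643%) were also less frequent at summits. CCGGAAGT was rare in both, at 0.126%. These 5 words were below their flanks by exact McNemar tests (adjusted p from 1.84e-22 for GGAT to 1.93e-04 for MGGAAR, Benjamini-Hochberg over 23 words), and each also passed in the peaks of each replicate alone. The longer of these words contain GGAA or GGAT, so the 5 results are not independent of each other. MGGAAR did not pass at TSS peaks (ratio 0.940, adjusted p = 0.829) or with flanks of the same GC content (0.922, adjusted p = 0.0548), nor CCGGATG in distal peaks (0.483, adjusted p = 0.363, exact McNemar tests). None of the 6 ETS words passed in the 500 strongest peaks.

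Words of other factors varied. The TATA box word TATAAAA was present at 7.84% of summits against 4.55% of flanks (adjusted p = 3.14e-14), and the DREF word TATCGATA at 0.908% against 0.321% (adjusted p = 7.58e-05, exact McNemar tests). The M1BP word GGTCACAC (0.657% against 0.258%), the BEAF-32 word CGATA (12.8% against 11.2%) and the GATA word WGATAR (19.0% against 17.0%) were higher too, with adjusted p of 0.0135, 0.0110 and 0.0251. E-boxes (CANNTG, 35.0% against 41.2%), the TEAD word GGAATG (3.12% against 4.70%) and the nuclear receptor half-site AGGTCA (1.79% against 2.49%) were lower. The GAGA factor word GAGAG was higher at summits in the conservative set (16.6% against 12.7%, exact McNemar test, adjusted p = 2.51e-08). Its ratio was 1.61 in the peaks of replicate 2, but 0.979 in those of replicate 1, where it did not pass. In the 500 strongest peaks the ratio was 0.480, and GAGAG passed as lower at summits (exact McNemar test, adjusted p = 0.00205). In those 500 peaks, windows of 51 bp held GAGAG in 3.20% of cases at the summit, 22.0% and 20.4% at 120 bp to either side, and 8% and 7.40% at 500 bp, values that were not tested. The words for Zelda, Ohler 6, AP-1, vri and Pdp1, Hox proteins, Runt and grainyhead and the CA repeat did not pass in the conservative set (adjusted p from 0.117 to 1).

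Several of these results depended on the peaks or flanks used. The Hox word TTAATKR was lower at summits in replicate 2 alone (ratio 0.771, adjusted p = 2.19e-06), in the other series-level set (0.887, adjusted p = 0.0239) and with flanks of the same GC content (0.741, adjusted p = 1.36e-10, exact McNemar tests). Its ratio was above 1 in replicate 1 alone (1.11), with flanks at 300 bp (1.03) and in the 500 strongest peaks (1.12), without passing. In replicate 1 alone, the Ohler 6 word (0.698), the CA repeat (0.675) and the Runt word (0.797) were lower (exact McNemar tests, adjusted p = 7.28e-04, 9.17e-04 and 0.0430). The Ohler 6 word was also lower in distal peaks (0.658, adjusted p = 0.00523), and the CA repeat against flanks at 300 bp (0.762, adjusted p = 0.0118) and in the 3578 strongest peaks (0.707, adjusted p = 0.0446, exact McNemar tests). With windows of 100 bp to each side of the summit, TTAATKR (0.890) and the Ohler 6 word (0.849) were lower (exact McNemar tests, adjusted p = 0.00101 and 0.0193). With flanks of the same GC content the TATAAAA ratio was 1.11 and did not pass (exact McNemar test, adjusted p = 0.104), and that of WGATAR was 0.952. In distal peaks TATCGATA occurred at only 5 summits and GGTCACAC at 9, and neither these words nor CGATA (ratio 0.968) or AGGTCA (0.871) passed. At TSS peaks WGATAR (0.930) and GGAATG (0.817) did not pass, and WGATAR did not in the other series-level set (1.07, exact McNemar test, adjusted p = 0.230). With flanks at 300 bp GGTCACAC (1.74) and AGGTCA (0.821) did not pass, nor CGATA with flanks at 1000 bp (1.06, exact McNemar tests, adjusted p = 0.146, 0.276 and 0.699). In the 3578 strongest peaks GAGAG (1.09), TATCGATA (2.48), GGTCACAC (15 summits), AGGTCA (0.705) and CGATA (1.06) did not pass (exact McNemar tests, adjusted p from 0.0898 to 0.780). In replicate 2 alone, CGATA (ratio 1.05), WGATAR (0.981) and GGAATG (0.784) did not pass, and in replicate 1 alone AGGTCA (0.770) did not (exact McNemar tests, adjusted p = 0.599, 1, 0.0501 and 0.0584).

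**Figure D4:**
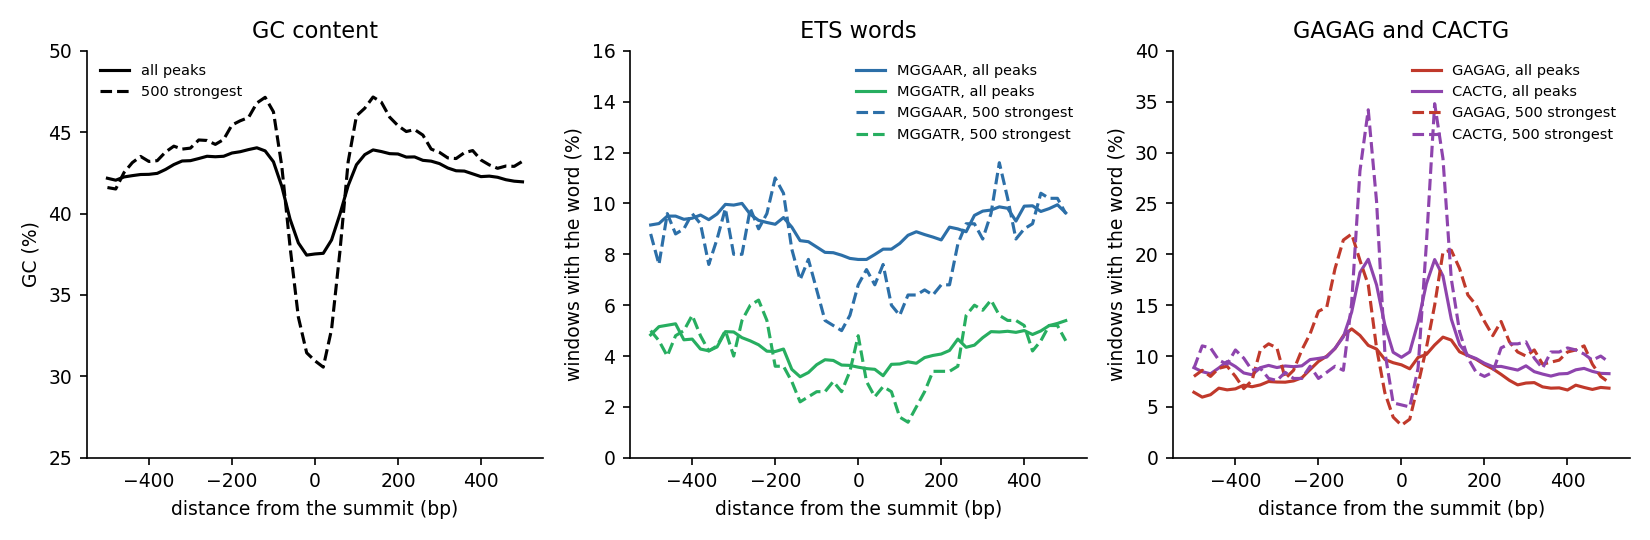
Sequence around peak summits, by distance from the summit (bp). Left, GC content (%); middle and right, share of windows (%) holding each word; solid lines are all 7157 peaks and dashed lines the 500 with the highest signal value, in which GC was 31.0% at the summit and CACTG reached 34.8% at 80 bp.

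The replicates shared most of their strong peaks. Of the 5850 peaks of replicate 1, 4563 (78.0%, 95% Wilson interval 76.9 to 79.0%) overlapped a peak of replicate 2 by at least 1 bp, against 3.35% after random placement. Of the 7963 peaks of replicate 2, 4762 (59.8%, interval 58.7 to 60.9%) overlapped one of replicate 1, against 2.54%. Both shares exceeded all 1000 placements (permutation p = 0.001, the smallest they can give). Of the 500 strongest peaks of each replicate, 381 (76.2%) were shared. Of the peaks found in 1 thresholded list alone, 85.2% of those of replicate 1 and 83.0% of those of replicate 2 overlapped a peak in the ranked list of the other replicate. No random placement was made for these 2 shares. The ranked lists are far longer (35793 peaks in replicate 1 and 47537 in replicate 2), so more overlap arises by chance than with the thresholded lists.

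Peaks in a single list had lower median signal values than shared ones. In replicate 2, peaks not overlapped had a median signal of 54.2, against 91.1 for shared ones, and 48.4% of them were at a TSS, against 38.9%. In replicate 1, peaks not overlapped had a median signal of 51.8, against 82.1, and 29.9% of them were at a TSS, against 38.9%. Across the 4563 pairs of overlapping peaks, signal values correlated with a Spearman rho of 0.724 and a Pearson r of 0.759 on the log scale. These are correlations across peaks, which are not independent replicates. No test was made of them or of the differences between shared and other peaks.

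**Figure D5:**
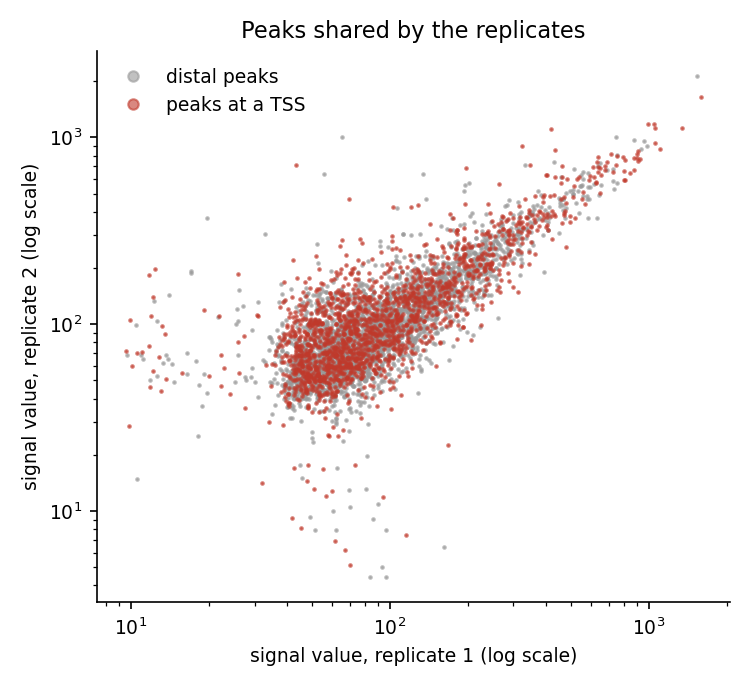
Signal value of replicate 2 against that of replicate 1 for the 4563 pairs of overlapping peaks, on log scales. Each point is a pair, red where the peak of replicate 1 is at a TSS and grey otherwise; the points rise together with a rho of 0.724.

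Peaks were spread over the large chromosome arms, with an excess on X and very few on chromosome 4. X held 1413 peaks against 1226 expected from its length (ratio 1.15), and 3L held 1578 against 1462 (ratio 1.08). Chromosome 4 held 2 peaks against 69.5 expected, and Y held 0 against 178. These 4 arms differed from their share of sequence by exact binomial tests (adjusted p = 1.96e-08, 0.00130, 9.27e-27 and 7.71e-78, Benjamini-Hochberg over 7 arms). Arms 2L (1243 peaks), 2R (1306) and 3R (1615) did not, with ratios of 1.01, 0.989 and 0.965 and adjusted p of 0.681, 0.681 and 0.143. When the expectation followed the number of protein-coding TSSs, 2L, 2R and 3R had ratios of 0.924, 0.893 and 0.957 and passed (exact binomial tests, adjusted p = 0.00203, 5.88e-06 and 0.0421).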

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

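The ranked lists also held peaks on sequences that are not placed on a main arm, which no comparison used; no tests were made of them, and they were counted after the lists had been seen. There were 24 such peaks of 38614 in the ranked list that holds the conservative peaks (on 20 sequences, highest signal 256) and 29 of 41426 in the other series-level ranked list. The ranked list of replicate 1 held 58 of 35793 (highest signal 158) and that of replicate 2 held 40 of 47537 (highest signal 153). Each number is above the 3 that a count of 0 allows, and no explanation was tested. Of the thresholded lists, that of replicate 1 held 1 such peak and the other 3 held 0. With 2 samples in 1 group, no sample could be tested as an outlier and no effect could be compared between groups.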

How the results depend on the processing

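Of 574 values recomputed under an alternative, 491 kept their side of the threshold, or for counts stayed within 1.5-fold; 35 lost a call, 29 gained one, 8 moved and 11 turned. The tests with the 500 strongest peaks, with flanks matched on GC and with repeated intervals counted once were chosen after the data had been seen. The TSS share stayed above random placements in all 9 alternatives, from 30.0% with a window of 200 bp to 49.1% with 1000 bp (36.9% to 42.7% with 1 replicate left out). The 78.0% overlap of replicate 1 by replicate 2 moved to between 63.6% and 82.7%, and the 59.8% to between 47.1% and 60.9%, all above chance. The rank correlation was 0.775 with 50% reciprocal overlap, 0.751 with summits within 100 bp and 0.689 over the ranked lists. The 5 ETS words below their flanks were 4 or 5 in all alternatives chosen beforehand and 4 with matched GC, but 0 in the 500 strongest peaks, where fewer peaks were tested (ratio 0.871 for GGAA and 0.783 for GGAT). The 5 gene lists became 8 with the other series-level set, 3 with the background of ranked peaks and 4 to 9 with 1 replicate left out; the cause was not tested. The number of arms that differed was 7 with expectation by TSSs, under which 2L turned to 0.924. The signal difference of 3.87 was 5.03 and past the threshold with the other set, and -3.15 with a window of 200 bp, short of the threshold. For main results such as this, a change of sign was counted as turned even where neither value passed. Of the 66 named genes with a TSS peak, 49 to 66 kept one (61 to 62 with 1 replicate left out). Among other words, ratios turned for GAGAG (0.979 to 1.61 with 1 replicate left out; 0.480 in the 500 strongest), CGATA (0.968 distal) and WGATAR (0.981 to 1.24 with 1 replicate left out; 0.930 at TSSs; 0.952 with matched GC); the cause was not tested. Ratios below 1 for TATCGATA (0.714 distal, 5 summits; 0.4 in the 500 strongest, 1 summit) and GGTCACAC (0 in the 500 strongest, 0 summits) rest on counts too small to show a change of direction. Of the 491, 59 crossed the line of no difference while past the threshold under neither setting; the decision to count these as unchanged was taken after the output had been seen. No paired analysis was possible because there is 1 group. Unknown depth limits what the absence of a peak shows.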

Other observations

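The tests of summit placement, of the 500 strongest peaks, of GC over wide windows and of the ranked list on chromosome 4, and the search for 6-letter words with its controls, were chosen after the patterns had been seen. The tests of matched flanks, word orientation, masked sequence and TSS numbers were written before their results.

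Peaks had a sequence layout that was more marked where signal was high. In 51 bp windows, CACTG was in 19.5% of all peaks at 80 bp to either side, and in 8.86% and 8.27% at 500 bp. In the 500 strongest it reached 34.2% and 34.8% at 80 bp, values that were not tested. In the 101 bp around the summit of all 7157 peaks, GC content was 37.7%, against 42.1% in flanks (difference -4.43 percentage points, 95% bootstrap interval -4.74 to -4.09), and the difference was -6.88 in replicate 1 and -1.52 in replicate 2. Over 10 equal groups of peaks by signal, summit GC was 43.4% in the weakest and 31.9% in the strongest. Beside the summits of the 1000 strongest peaks, 6-letter words were sought in 500 peaks and tested in the other 500. ACAGTG occurred about 100 bp from the summit in 28.2% of the tested peaks and about 600 bp away in 7.60% (adjusted p = 1.56e-16, exact McNemar test over 12 words), and CAGTGG in 23.0% and 7.80% (adjusted p = 2.29e-10). At the summits themselves the leading words were AT-rich, such as TTAAAA (28.4% against 13.8%, exact McNemar test, adjusted p = 1.22e-07). The far windows were not matched on GC, so this test does not separate such words from the low GC of the summits.

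The AT-rich centre deepened with signal (Spearman rho -0.290 across peaks, 95% interval -0.311 to -0.269). A preference of amplification or sequencing for AT-rich fragments was examined by GC over 601 bp, which had a rho of -0.00558 with signal (-0.0288 to 0.0176). This argues against such a preference for fragments of about that length only. In the 500 strongest peaks, GC was 31.0% at the summit and 47.1% and 46.5% at 120 bp to either side, which can cancel over 601 bp. A preference among shorter fragments, which start at 200 bp, was not tested. A hypothesis is that many summits may lie between transcription starts that point away from each other: the initiator word TCAGT, 50 to 150 bp from the summit, pointed outward 781 times and inward 488 times in peaks at a TSS (ratio 1.60, exact 95% interval 1.43 to 1.80) and 1287 against 756 times in distal peaks (ratio 1.70, 1.56 to 1.86). At 450 to 550 bp the ratios were 1.07 (0.938 to 1.22) and 0.979 (0.886 to 1.08), and for the reversed letters TGACT beside the summit they were 0.901 (0.778 to 1.04) and 1.21 (1.09 to 1.35), so part of the asymmetry at distal peaks was not particular to the initiator word. TCAGT is also part of TCAGTG, which was found beside the summit in 18.2% of the tested strong peaks and far from it in 6.8%. Words were counted over both sides of all peaks together, so summits upstream of a single start would also give a ratio above 1. The ratios therefore do not separate an initiator from another oriented word, or paired starts from single ones. Transcription was not measured in these samples, and shearing preferences at the summit itself stay open.

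The ETS words were less frequent at summits than in flanks. GC content as the whole cause is argued against by flanks with the same number of G and C bases. The ratio there was 0.928 for GGAA (95% bootstrap interval 0.8996 to 0.957, and 0.891 unmatched) and 0.855 for GGAT (0.816 to 0.892, and 0.788 unmatched), although matching reduced both deficits. Such deficits were not particular to ETS words. Against the same flanks, 4 words of other factors were lower by exact McNemar tests (TTAATKR 0.7415, AGGTCA 0.762, GGAATG 0.794 and CANNTG 0.920) and 4 were higher. Of the lower words, GGAATG contains the core GGAA, so its deficit is not separate from that of GGAA. The coding share of the flanks was not matched. Summits placed at a common distance and side from the site are argued against by a scan of single windows within 200 bp. The highest share was 1.01 times that at 500 bp for MGGAAR (0.918 to 1.09) and 0.836 times for MGGATR (0.734 to 0.956). Sites on either side or at varying distances would be spread over these windows, and GC was not matched, so that case was not settled. With windows of 100 bp to each side of the summit, the ratios to flanks were 0.869 for MGGAAR and 0.723 for MGGATR. For dilution by weak peaks, the ratios in the 500 strongest peaks were 0.684 (0.514 to 0.879) and 0.673 (0.458 to 0.972), so no excess was seen there. These flanks were not matched on GC, which was 31.0% at the strongest summits and 41.6% and 43.2% at 500 bp to either side. Neither word passed in these peaks by exact McNemar tests (adjusted p = 0.136 and 0.433), so dilution was not settled. No biological explanation was tested, since both samples belong to 1 group. Recruitment through other proteins, and signal that does not depend on the tagged factor, stay open, as no sample without the tag was analysed here.

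Chromosome 4 held 2 peaks, at the TSSs of PlexA (1027195 to 1027393, signal 264) and gw (659938 to 660317, signal 155). The authors' threshold and later filters are argued against by their ranked list, which held 8 peaks there, 0.0214 of the 375 given by length (exact 95% interval 0.00922 to 0.0421). Repeats are argued against by unmasked sequence, with 0.0317 of the expected 63.2 peaks (0.00383 to 0.114), and a lack of TSSs by 0.0379 of the expected 52.7 (0.00459 to 0.137). Treatment of chromosome 4 reads before peaks were ranked, and a real scarcity of binding, stay open, and no biological explanation was tested. On Y, which had no peak in the conservative set, 53.3% of sequence is masked as repeats, against 28.1% on chromosome 4.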
